A study of Picea abies with 25 samples.

How the data were processed

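RNA from the cambium of Norway spruce (Picea abies) was compared on 25 2-colour cDNA microarrays. Per the labels' protocols, total RNA was copied into cDNA by a PCR-based method from 1 microgram of RNA and labelled with Cy5 or Cy3 by a Klenow method. Both channels of each array held a sample of the study, so the arrays form a loop with no common reference. The labels put 20 RNA samples into 8 groups. There were 3 healthy and 3 infected samples from each of 3 clones of low, medium and high resistance to the fungus, and 1 wounded sample from each of the low and medium clones. Harvest was at 20 days in the labels' protocols, while the text on the series' design speaks of 1 month. The species of the fungus is Heterobasidion parviporum in the labels' protocols, and the series' title names another species of the genus.

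The deposited scan files give, per the file headers, spot and local background intensity values from QuantArray with histogram quantification, not background subtracted and not corrected for crosstalk. Each array had 5376 spots in 48 sub-grids, 12 rows by 4 columns, each of 8 by 14 spots. The scanner software had marked 4618 of 134400 spot records (3.44%) to be ignored, from 3 to 923 per array, and these were left out. The scan files hold 0 spot names and no other table used here pairs spots with genes, so gene names are not given and the gene lists chosen before the data were examined could not be applied. The authors also deposited 1 processed value per spot and array. Set against the scanner signals, this value fell as Cy5 over Cy3 rose (r between -0.95 and -0.62 per array), so it ran as Cy3 over Cy5. Column medians lay between -0.01 and 0.01. The slope on the log10 ratio lay between -0.37 and -0.15, so the scale and log base remain unknown. The deposited values were used, with the sign turned, only as an alternative.

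Pairs of side-by-side sub-grids held the same pattern of brightness. Mean log2 brightness correlated at 0.97 to 0.99 within these pairs, and at 0.49 or less with any other sub-grid. The 2 spots of such a pair were taken as duplicates of 1 probe, an inference from the data, giving 2688 probes, which are named here by their 2 spot numbers. Signals were corrected with normexp (offset 50) and log2(Cy5/Cy3) was normalised within arrays by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Duplicate spots were averaged. The 155 probes with both spots ignored on at least 1 array were left out and 2533 were tested.

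Each comparison used a fit in 2 stages. Least squares over the loop, with a dye term per probe, gave 1 value for each RNA sample. A group model on the 20 values, weighted by the covariance that the loop gives, was then tested with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The ratio of RNA-sample to array variance was pooled over probes by restricted maximum likelihood and came to 0. At 0 the weights treat RNA samples of a group as differing by array error alone. Other settings gave ratios of up to 0.18. The residual degrees of freedom were 12 and the prior degrees of freedom 9.78. All groups shared 1 estimate of the spread, and the lone wounded sample of a clone was assumed to vary like the other groups. The series' design text describes the infected samples as separate plants (ramets) of a clone. It does not say this of the healthy samples, so p-values measure the spread between the RNA samples whatever its source.

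The method was tested on simulated data with the same loop, 2500 probes and 200 changed ones. For infected against healthy over the 3 clones, 95 of 100 probes with a log2 change of 0.5 and 100 of 100 with a change of 1 were recovered when RNA samples varied no more than arrays allow, and 51 and 97 when the variance ratio was 0.5. For infected against healthy in the low clone alone the counts were 50 and 97, and 2 and 49 with that ratio. For the response of the high minus the low clone they were 17 and 74, and 0 and 2. False calls were at most 6.19% of all calls in these simulations. The simulated noise was independent between probes and followed the model that was fitted. Correlation between adjacent spots and the poor repeatability of real arrays, described below, were not simulated. The rates of false calls and recovery may therefore not hold for the real data.

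Each RNA sample was also scored by projecting its fitted values on the mean infection response of the other clones, less the healthy mean of its clone. The score that noise in shared arrays alone gives in simulations of the same loop was subtracted.

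Probes were named by a rule fixed before the data were examined. In the absence of gene names it allows at most 2 probes that rose and 2 that fell, taken here as the 2 largest rises and 2 largest falls among probes past the threshold for the mean of the clones with 1 direction in all 3 clones. Alternatives fixed then were no background correction, print-tip loess, median centring without loess, a filter on dim probes, ignored spots kept, the authors' values, the 25 arrays taken as independent, no dye term, a dye term for each of 2 slide series, the sample number as a block, equal weights, and leaving out each RNA sample. Removal of a 2-dimensional smooth (span 0.05) from each array, a dye term for each of 3 scan batches and leaving out an array with poor duplicates were added after seeing the data.

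The repeatability of single arrays was limited. Median spot signals per array lay between 496.4 and 2810 in Cy5 and between 609.7 and 3031 in Cy3, against median local backgrounds of at most 100.1 and 338.3, and 0 spots lay at or below their own local background. Duplicate spots correlated at 0.34 to 0.75 per array in log2 ratio, and adjacent spots, which hold different probes, at 0.08 to 0.63. Among the 4 pairs of arrays that repeat the same RNA samples with dyes exchanged, where a correlation near -1 would mark full repeatability, the values were 0.00, -0.06, -0.14 and -0.55, and -0.425, -0.388, -0.324 and -0.657 with print-tip loess. All 4 pairs hold a wounded sample, so they bear most directly on the comparisons with wounded tissue and between clones. No array of infected and healthy RNA was repeated with dyes exchanged, so repeatability there was not measured this way.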

Results

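The study followed transcripts in the cambium of Norway spruce after stem inoculation with Heterobasidion parviporum, a fungus that causes root and butt rot of conifers. Plants of 3 clones of low, medium and high resistance were cut and inoculated with fungus on agar, or cut and given agar alone, and harvested after 20 days. Healthy tissue served as the control. In all, 9 infected, 9 healthy and 2 wounded RNA samples were hybridised to 25 arrays, and 2533 probes were compared. On 15 arrays infected and healthy RNA of the same clone met directly, 9 with infected RNA in Cy5 and 6 with it in Cy3. The other 10 arrays carried a wounded sample and joined the clones.

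The first comparison asked which transcripts differed between infected and healthy tissue, whatever the clone. Infected plants had been cut as well as inoculated, so it does not separate the fungus from the cut. The infection response below covers both. Averaged over the 3 clones, 220 probes were higher and 196 lower in infected than in healthy cambium (416 in all, 16.4% of those tested; limma, adjusted p below 0.05). Most changes were modest, with a median log2 change of 0.48 among the probes that rose and -0.48 among those that fell. At least a 2-fold change was reached by 18 of the risen and 9 of the fallen probes. Of the 416 probes, 399 (95.9%) had the same sign in all 3 clones, although they were chosen on the mean of the same clones, which favours a common sign. Of all probes tested, with no choice, 46.5% had 1 sign in all 3 clones. The count stayed within 1.5 times 416 under 10 of 14 settings of the processing. It moved to 222 with no background correction and 216 with the authors' values. With the sample number as a block it was 244, and with equal weights for the RNA samples 28. The count also fell in all 20 fits that left out 1 RNA sample with its arrays, to between 201 and 391. Loss of data can lower it in any case, so these fits do not show that particular samples drove the response. The pooled variance ratio also changed in some of them, to 0.18 without healthy sample 2 of the medium clone. The fits in which the count fell by more than 1.5 times follow. In the low clone it was 255 and 239 without healthy samples 2 and 3, and 260, 243 and 263 without infected samples 1, 2 and 3. In the medium clone it was 201 and 259 without healthy samples 2 and 3, and 260 and 246 without infected samples 1 and 2. In the high clone it was 272 and 235 without healthy samples 1 and 2, and 251 without infected sample 2.

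**Figure D1:**
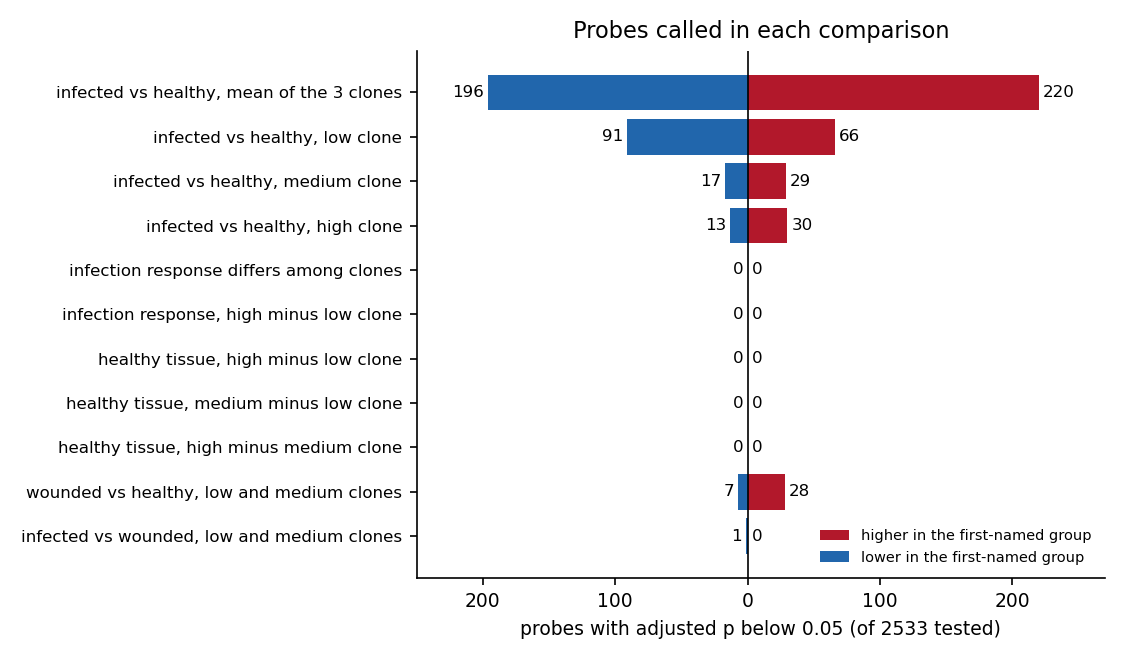
Number of probes past the threshold in each comparison (horizontal axis, probes; red bars to the right higher, blue bars to the left lower in the first-named group, with the count beside each bar). The mean of the 3 clones gave 220 higher and 196 lower probes, and the comparisons between clones gave 0.

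The probes named here were chosen as extremes of a fit to the same arrays, which favours a common direction on single arrays. Some RNA samples were also on more than a single direct array, so the 15 arrays are not 15 replicates. The largest rise was at the probe printed at spots 3587 and 3699, which was 2.79-fold higher in infected tissue (log2 change 1.48, SE 0.13, adjusted p = 2.12e-07 in limma) and higher on 15 of the 15 direct arrays. Its level was -1.07 ± 0.40 in healthy and 0.63 ± 0.27 in infected tissue of the low clone (log2, relative to the mean of the 20 samples; SD, n = 3 each). In the high clone the levels were -1.14 ± 0.09 and 0.04 ± 0.55 (SD, n = 3 each). The probe at spots 1849 and 1961 rose 2.54-fold (log2 change 1.34, SE 0.13, adjusted p = 1.30e-06 in limma), again on 15 of 15 arrays, and by 1.57, 1.08 and 1.37 in the low, medium and high clones.

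The largest fall was at the probe at spots 1656 and 1768, with a log2 change of -2.12 (SE 0.25, adjusted p = 7.10e-06 in limma), that is, to 0.23 times the healthy level, on 14 of 15 direct arrays. This probe was bright, at the 98.5th percentile of mean signal. It fell by 2.87 in the low and by 2.12 in the medium clone. In the high clone the change was -1.36 and did not pass the threshold (adjusted p = 0.115 in limma), and the difference between the high and low responses did not either (1.52, SE 0.63, adjusted p = 0.935). Its replicates were uneven, with -0.97 ± 1.08 in infected against 1.73 ± 1.97 in healthy tissue of the low clone (SD, n = 3 each). The probe at spots 985 and 1097 fell by 1.54 (SE 0.13, adjusted p = 1.37e-07 in limma) and was lower on all 15 direct arrays, with 1.10 ± 0.26 in healthy and -0.74 ± 0.65 in infected tissue of the high clone (SD, n = 3 each).

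**Figure D2:**
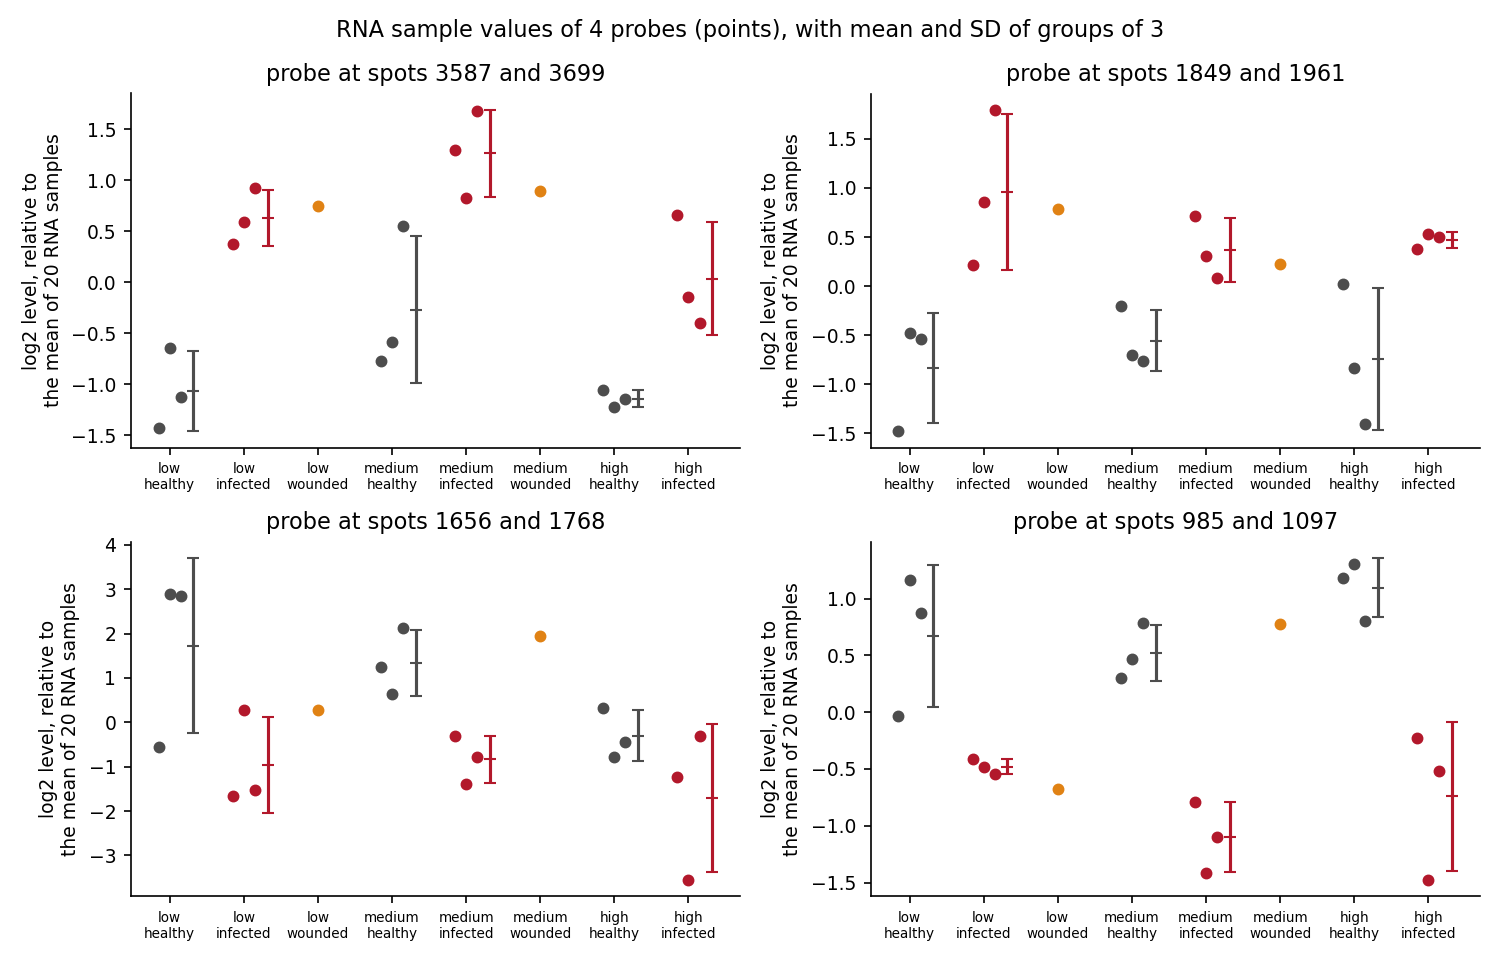
Level of the 4 named probes in each RNA sample (vertical axis, log2 relative to the mean of the 20 samples; grey healthy, red infected, orange wounded; bars, mean and SD of groups of 3). For the probe at spots 985 and 1097, the healthy mean of the high clone was 1.10 and the infected mean -0.74.

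The infection response was recomputed within technical batches from the direct arrays. In the first series of slides (6 direct arrays) the risen probes had a median log2 change of 0.56 and the fallen ones -0.59. In the second series (9 arrays) the medians were 0.44 and -0.47. In the 3 scan batches, of 6, 5 and 4 direct arrays, the risen probes had medians of 0.48, 0.48 and 0.46 and the fallen ones -0.55, -0.50 and -0.42. These probes had been chosen on all arrays together. Over all 2533 probes, with no choice, the responses of both slide series correlated at 0.75, and those of the scan batches at 0.54 to 0.56; probes are not independent replicates, and some RNA samples were on slides of both series. A dye term for each slide series gave 396 calls, and a dye term for each scan batch 348.

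The second comparison asked how each clone responded. The low clone had 157 called probes, 66 higher and 91 lower in infected tissue. The medium clone had 46, of which 29 were higher and 17 lower, and the high clone had 43, of which 30 were higher and 13 lower. On the common set of 220 risen and 196 fallen probes, the median log2 changes in the low, medium and high clones were 0.57, 0.44 and 0.51 for the risen and -0.64, -0.40 and -0.46 for the fallen ones. In all, 195 probes were called in at least 1 clone, 29 in exactly 2 clones and 11 in all 3. With median centring in place of loess, the split was 7 higher to 1 lower in the medium clone and 12 to 1 in the high clone. With the authors' values it was 19 to 4 in the high clone. No clone had a firm excess in 1 direction, since the split turned to 16 higher and 36 lower in the high clone without its healthy sample 3. In the low clone it turned to 23 to 7 without its healthy sample 2 and to 27 to 14 with the sample number as a block, and in the medium clone to 23 to 28 with a dye term for each scan batch. With equal weights for the RNA samples the low, medium and high clones had 0 calls each in limma (111, 47 and 66 at an unadjusted p below 0.05), and with the sample number as a block 41, 8 and 13. The counts moved when single samples were left out with their arrays, those of other clones included, through the shared estimate of spread and the loop. Loss of data alone can lower them. The low clone gave 30 and 12 calls without its healthy samples 2 and 3, and 64, 14 and 38 without its infected samples 1, 2 and 3. It gave 95 without its wounded sample, 91 and 87 without healthy and infected sample 2 of the medium clone, and 88 without healthy sample 1 of the high clone. The medium clone gave 24, 0 and 4 calls without its healthy samples 1, 2 and 3, and 14, 6 and 6 without its infected samples 1, 2 and 3. It gave 30 without the low-clone wounded sample and 24 without healthy sample 1 of the high clone. The high clone gave 17 and 7 calls without its healthy samples 1 and 2, and 85, 4 and 10 without its infected samples 1, 2 and 3. It gave 25 without the low-clone wounded sample, and 25 and 21 without healthy and infected sample 2 of the medium clone.

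The responses of the clones ran together. Across the 2533 probes, which are not independent replicates, log2 changes correlated at 0.49 between low and medium, 0.56 between low and high, and 0.52 between medium and high. Simulated arrays of the same loop with no response gave mean correlations of -0.04, -0.04 and 0.07. The covariances were 0.07, 0.08 and 0.06, against 0.00 in each of these simulations. Low and high shared 16 called rises, where independent lists would share 0.78, and 5 called falls, where they would share 0.47. No probe was called in opposite directions in a pair of clones (0 in each of the 3 pairs). Independent lists this short would share few such calls as well, so this count says little.

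**Figure D3:**
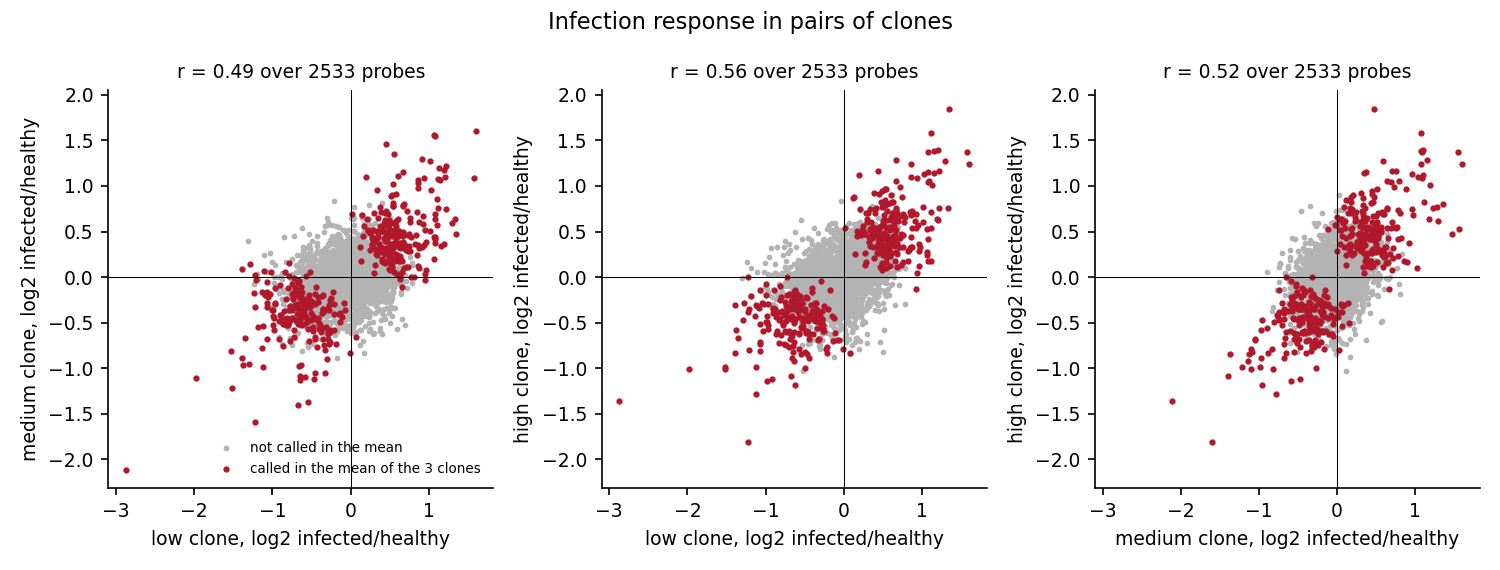
Log2 infected over healthy level of each probe in pairs of clones (both axes log2; red points, the 416 probes called in the mean of the clones; grey points, the rest). The correlations over all 2533 probes are 0.49, 0.56 and 0.52.

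The third comparison asked whether the clones, which differed in resistance, responded differently. Each level of resistance was a single clone, so resistance cannot be told apart from other differences between the clones. No probe passed for a response that differed among the 3 clones (0 in limma's moderated F test, 125 at an unadjusted p below 0.05, where 127 are expected by chance). None passed for the high minus the low clone (0 in limma, 103 at an unadjusted p below 0.05). The fit to 25 independent arrays also gave 0. At a variance ratio of 0 the main fit gives the same estimates as that fit, so it is not a separate check. The count of calls in the low clone therefore stood above the others without a probe for which the difference itself passed. The median 95% interval of a single probe's high-minus-low response, with no adjustment for the number of probes, spanned 0.68 on either side on the log2 scale. In simulated data 17 of 100 differences of 0.5 and 74 of 100 differences of 1 were recovered, and 0 and 2 when RNA samples varied with a variance ratio of 0.5, so differences of these sizes could be missed. Without healthy sample 3 of the high clone, 1 probe passed in each of these tests.

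The fourth comparison set healthy tissue of the clones against each other. No probe differed between the high and low, medium and low, or high and medium clones (0 each in limma). At an unadjusted p below 0.05 there were 55, 203 and 222 probes, with 127 expected by chance. The fit to 25 independent arrays gave 0 as well, but its estimates are the same as those of the main fit, so it adds no separate check. Clones were joined only through the wounded samples, and the median 95% interval of a single probe, with no adjustment for the number of probes, was wide, at 1.01, 1.01 and 0.84 on either side. Without wounded sample 1 of the medium clone 12 probes passed between high and medium, and without infected sample 3 of the high clone 56. Between medium and low 1 probe passed without infected sample 1 of the medium clone, and 144 passed with equal weights for the RNA samples.

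The last comparisons asked how much of the response wounding alone brings. Of the 220 probes that rose over the 3 clones, 213 had a fitted wounding change in the same direction. Of the 196 that fell, 160 did. In the low and medium clones the risen probes had median log2 changes of 0.503 with infection and 0.424 with wounding. The fallen ones had -0.507 and -0.295. These probes were chosen on a mean that shares healthy samples with the wounding comparison, which favours agreement. Wounded tissue of the low and medium clones had 28 higher and 7 lower probes than healthy tissue (35 in limma). Of these 35, 33 were also called, in the same direction, for infection over the 3 clones, a comparison that shares healthy samples with this one. The high clone shares no healthy sample with it, but its samples met both wounded ones on arrays. In that clone 32 of the 35 had the same sign for infection. Over all probes 60.7% did, against 50.3% in simulated arrays with no effect. In the high clone 11 rises and 1 fall were called in both, where independent lists would share 0.33 and 0.04. That expectation leaves out the shared arrays. The probe at spots 3587 and 3699 was 3.33-fold higher in wounded tissue (adjusted p = 0.00118 in limma), and that at 1849 and 1961 2.09-fold (adjusted p = 0.0346). The 2 probes with the largest falls in infected tissue did not pass for wounding. At the probe at spots 1656 and 1768 the fitted wounded-minus-healthy change was 0.42 (SE 0.47, adjusted p = 0.823 in limma), but the plain means of the samples differed by -1.44 in the low and 0.61 in the medium clone, so the fit and the means gave no common direction. At 985 and 1097 the fitted change was -0.23 (SE 0.24, adjusted p = 0.797). At the latter probe the wounded samples stood apart, at -0.67 in the low and 0.78 in the medium clone. The split of 28 to 7 moved to 2 to 0 with median centring, 11 to 1 with the authors' values and 5 to 0 with no background correction.

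Infected and wounded tissue of these clones differed at a single probe, 1656 and 1768, which was lower in infected tissue by a log2 change of -2.92 (SE 0.47, adjusted p = 0.00822 in limma). The plain means differed by -1.25 in the low and -2.77 in the medium clone, both smaller than the fitted change, which weights the samples by their place in the loop. At an unadjusted p below 0.05 there were 137 probes, with 127 expected by chance. The wounding response correlated at 0.44 with the infection response of the high clone, which shares no healthy sample with it (0.01 in simulated arrays with no effect; covariance 0.05 against 0.00). The wounded samples differed here. Taken alone, the low-clone one gave 0.44 (covariance 0.09 against -0.01) and the medium-clone one 0.09 (covariance 0.01 against 0.01). With the low and medium clones, whose healthy samples it shares, the correlations were 0.53 and 0.57, against 0.23 and 0.22 in the simulation, and the covariances 0.08 and 0.06 against 0.01 and 0.01. Healthy samples could not be split into sets of at least 2 per clone, so these 2 correlations are not free of the shared controls. The single call between infected and wounded tissue was absent with print-tip loess, with median centring and with equal weights.

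The low and medium clones had 1 wounded sample each, and the 35 wounding calls moved to 0 without the low-clone and 1 without the medium-clone one. In the low clone they moved to 1 and 20 without healthy samples 1 and 2, and to 14 and 7 without infected samples 1 and 3. In the medium clone they moved to 0 and 6 without healthy samples 1 and 2, and to 2 without infected sample 2. They came to 16 without healthy sample 1 and 17 without infected sample 3 of the high clone. The call between infected and wounded tissue became 0 without healthy sample 1 of the low clone, healthy samples 1 and 2, infected sample 2 or the wounded sample of the medium clone, or healthy sample 1 of the high clone. It became 2 without healthy or infected sample 2 of the high clone. Without the low-clone wounded sample the call at spots 1656 and 1768 was lost and another probe passed.

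Each RNA sample was also scored on the mean infection response of the clones other than its own. Here 0 is the healthy mean of its clone and 1 the fitted response of the other clones. Noise in that fitted response pulls scores towards 0, so a sample with the full response can score below 1. Each clone was scored on a different response, so scores of different clones cannot be compared directly. Infected samples scored 0.93 ± 0.04, 0.57 ± 0.08 and 0.64 ± 0.18 in the low, medium and high clones (SD, n = 3 each). Healthy samples lay between -0.16 and 0.13. The mean difference was 0.711. A permutation of the finished scores within clones gave p = 0.00025 for a difference of this size in either direction, the smallest that 8000 arrangements allow. The scores kept the weights from the real labels of the other clones, and samples share arrays. This p is therefore not exact and may be too small. The wounded sample scored 1.18 in the low clone and 0.00 in the medium clone, with no replicate of either. Before the expected score was subtracted, median centring put the low-clone wounded sample at 0.68, where the healthy samples of its clone reached 0.77.

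**Figure D4:**
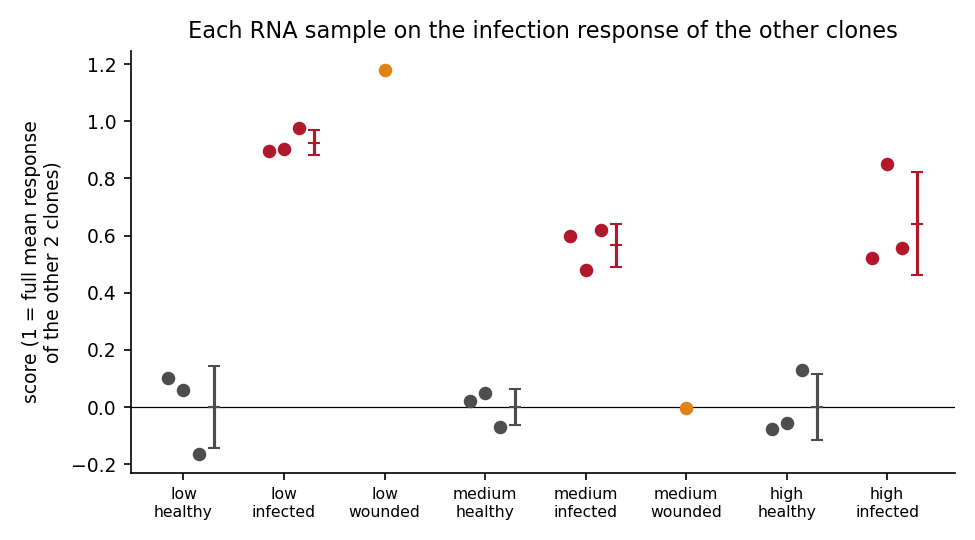
Score of each RNA sample on the infection response of the other clones. On the vertical axis, 1 is the mean fitted response of the other clones and 0 the healthy mean of the clone. Grey points are healthy, red infected and orange wounded samples. Bars give mean and SD of groups of 3. The low-clone wounded sample lies at 1.18, above the infected samples of its clone, and the medium-clone wounded sample at 0.00, among the healthy ones.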

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

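The alternatives with a smooth, with a scan-batch term and without 1 array were chosen only after the data were seen.

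The 4 named probes kept their direction and passed the threshold for infection over the 3 clones under all 34 settings tried, left-out samples included. They were chosen as the largest changes and the settings reuse the same arrays, which favours this. The count for the 3 clones lay between 28 and 547 and stayed within 1.5 times 416 under 10 of 14 settings. It moved to 222 with no background correction, 216 with the authors' values, 244 with the sample number as a block and 28 with equal weights for the RNA samples, a setting that ignores how far apart samples lie in the loop. The low, medium and high clones gave 72, 21 and 22 calls with no background correction and 79, 20 and 23 with the authors' values. With print-tip loess they gave 258, 76 and 65, and with equal weights 0 each. Median centring gave 8 in the medium and 13 in the high clone. The low and high clones gave 254 and 66 after removal of a 2-dimensional smooth, and the high clone 65 with the arrays as independent and 72 with a dye term per scan batch.

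Wounded against healthy gave 5 probes with no background correction, 69 with print-tip loess, 2 with median centring, 12 with the authors' values, 19 with no dye term, 0 with equal weights, 61 after the smooth and 14 without the array of poorest duplicates. Infected against wounded gave 2 with no background correction and with the arrays as independent, and 0 with print-tip loess, median centring, equal weights and without that array. Healthy medium against low gave 144 with equal weights and 1 after the smooth. The cause of these shifts was not tested.

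Leaving out 1 RNA sample gave 201 to 391 calls over the 3 clones, 12 to 185 in the low, 0 to 58 in the medium and 4 to 85 in the high clone. The range was 0 to 1 for both tests of differing responses, 0 to 0 for healthy high minus low, 0 to 1 for medium minus low, 0 to 56 for high minus medium, 0 to 50 for wounded against healthy and 0 to 2 for infected against wounded. Without 1 wounded sample the wounding comparisons used the other clone alone.

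The sample numbers were not taken to pair infected and healthy samples. Same-number samples deviated together with r between 0.03 and 0.68 over 9 pairs (mean 0.43), where shared arrays alone gave 0.44 in simulation. Of the 9 infected samples, 6 correlated best with their own number. Shared arrays alone made the own number the best for each of the 9 in simulation, so this count is no sign of pairing. The block on the number gave 244 calls over the 3 clones and 41, 8 and 13 in the low, medium and high clones. It could not be fitted for comparisons between healthy clones or with wounded samples. The gene list tests and their alternatives were not run, since no gene names were used here. Signals exceeded local background at every spot, but the median over arrays of the local background was 0 in Cy5, so this does not measure detection.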

Other observations

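The tests of slide trends, both tests on the low-clone wounded sample, the scores of single arrays, the counts of all clones without 1 of their own samples and the tests of wounding within each clone were chosen only after the result was seen, as were the wording of the test of exchanges for high minus low and the reading of the fungal, swap and healthy-range tests over 6 settings.

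Uneven use of the dyes would give probes that change sign with the dye of the infected sample, yet 99.8% of the 416 called probes had the same direction with infected RNA in Cy5 and in Cy3, and over all 2533 probes, with no choice, 63.8% did (r = 0.49, where dye alone would give a negative r). Trends across the slides are argued against as the whole source, since 91.8% of the called probes were called in the same direction after a 2-dimensional smooth was removed. With print-tip loess 328 of the 416 were. Adjacent spots still correlated at up to 0.314 after the smooth, so some trend remained. RNA of the fungus could raise probes in infected tissue alone, and over the 220 risen probes infected minus wounded was -6.24% of infected minus healthy in the low clone and 39.8% in the medium clone. Both met the bound of 50% set beforehand, but that bound took no account of the processing, and over 6 settings the low-clone value stayed between -19.9% and 18.5% while the medium-clone value reached 107% with the authors' values. The low-clone values argue against fungal RNA only if that wounded sample held no fungus, so it stays open, as does a response of the tree.

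Among 100 relabellings of infected and healthy samples within the clones, the real labels alone (1 of 100) gave as many as 416 calls. The highest of the others gave 22. Under the real labels every direct array sets infected against healthy. Most relabellings put like labels on some of these arrays, so they are estimated less precisely and favour fewer calls. The test argues against chance for that count but does not exclude it, and the splits below share this limit. Within 1 clone, 3 samples against 3 make 10 splits, too few for a share under 0.05. The real counts of 157, 46 and 43 in the low, medium and high clones stood against highest other splits of 3, 0 and 86, with 1, 1 and 2 of the 10 splits reaching the real count. The split with 86 exchanged infected and healthy sample 1 of the high clone, and no reason for it was tested.

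The low clone had the most calls, 157 against 46 and 43. Noisier values in the low clone are argued against by its within-group variance, 0.878 times that of the higher of the other clones. Without 1 of its own samples the low clone had 12 to 117 calls, the medium clone 0 to 24 and the high clone 4 to 85 (medians 34, 6 and 13.5), so a single sample as the source of the excess is left open. A larger response in the low clone is a biological hypothesis, and on the medium clone's response the low and high clones scored 0.67 and 0.45, a difference of 0.22 with an exact two-sided permutation p of 0.245. That p met the bound set beforehand against the hypothesis, but the bound was wrong, since a p above 0.05 from 3 infected samples per clone does not exclude a difference of this size, so the hypothesis stays open.

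A real count of 0 is reached by every split, so the following counts decide nothing. For responses that differ among the clones, 100 of 100 exchanges of clone labels among infected samples gave at least the real count of 0 (highest other 2), as did 20 of 20 for high minus low (highest other 0). For healthy tissue, where 10 splits are too few for a share under 0.05, 10 of 10 reached the real count of 0 in each comparison. The highest other was 0 for high against low, 0 for medium against low and 12 for high against medium.

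The wounded samples of the low and medium clones stood apart on the infection response. On single arrays, scored on the response of the 15 direct arrays, the low-clone wounded sample lay above healthy sample 1 of the high clone by 0.48 in Cy3 and 1.41 in Cy5, and above healthy sample 1 of the medium clone by 0.51 in Cy3 and 1.28 in Cy5. It lay 0.24 above an infected sample of its own clone on 1 array. The medium-clone wounded sample differed by -0.69 in Cy3 and -0.18 in Cy5 from infected sample 3 of the high clone, and by -0.45 and -0.41 from infected sample 2 of its own clone. From healthy sample 1 of the low clone it differed by -0.10 on 1 array. The healthy partners were of other clones, so these values mix wounding with clone, and they moved with the dye. By clone, limma called 0 probes for wounding in the low clone, 11 in the medium clone and 0 for the difference (307, 255 and 271 at an unadjusted p below 0.05). These tests rest on 1 wounded sample per clone, assumed to vary like the other groups, and do not decide whether the clones differ.

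Slide trends are argued against by the score of the low-clone wounded sample after the smooth, 0.918, where healthy samples reached 0.10, while a swap with an infected sample stays open, since the lowest infected score of that clone was 0.897, or 0.87 before the expected score was subtracted, but with median centring, also before it, 0.61 against a highest healthy one of 0.77. The medium-clone sample lay inside the healthy range of its clone (-0.0525 from the highest), but, before subtraction, above it with print-tip loess (0.15 against 0.10) and after the smooth (0.205 against 0.196). It moved with 25 of the 30 probes that rose and 11 of the 13 that fell in the high clone. Over the 3 clones it moved with 161 of the 220 that rose and 112 of the 196 that fell. The latter probes were chosen on a mean that uses the same healthy samples of its clone, which favours agreement. Over all 2533 probes its covariance with the high clone's response was 0.0144, where 0.0142 comes from noise alone. Whether this sample shares part of the response stays open. With 1 healthy sample per clone in place of 3, infected against healthy fell from 270 calls to a median of 26 over 9 choices, from 4 to 199 (167 to 615 at an unadjusted p below 0.05), while infected against wounded in the same fits gave 0 calls (47 to 93 at an unadjusted p below 0.05) in limma, so too few wounded samples could hide a smaller difference than that from healthy tissue. A wrong label of another kind, fungus reaching the wounded plant and a stronger wound response of the low clone stay open and untested, with 1 sample.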
